A study of Mus musculus with 4 samples.

How the data were processed

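Total RNA had been extracted from mouse trophoblast stem cells after up to 7 days without FGF4 and heparin, and stranded poly(A) libraries were sequenced as read pairs on an Illumina HiSeq instrument, per the labels' protocols, which give the read length inconsistently. The groups, WT and Tet2-KO with 2 libraries each, were taken from the sample labels. Each library had an FPKM table and a count table, with replicates kept separate.

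Per the submitters' processing notes, TopHat 1.3.3, Cufflinks 1.2.0, HTSeq 0.6.0 and edgeR were used with genome build mm9, without a stated role or order. The deposited FPKM tables have the columns of a Cufflinks gene table per the file headers, with an FPKM, a lower and an upper confidence limit and a status for each of 23011 loci. Of these, 444 carry no gene symbol and hold 0.434% to 0.467% of the summed FPKM. They were left out of the tests. For 43 symbols listed at more than 1 locus the locus with the highest mean was kept, leaving 22517 symbols. Between 1 and 7 loci per library had a failed status, including Dnmt1 in WT replicate 1. Hmgcs1 is listed at 0 in every library, so an exact 0 can be a failed estimate. Multi-copy genes can exchange reads, and whether Cufflinks used strand is not given in the sources used here. Coordinates are those of the deposited tables (mm9), given from base 1.

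The deposited count tables give whole-number counts of reads per RefSeq transcript accession, per the values and the HTSeq summary lines. Only 304171 to 349278 reads per library, 1.38% to 1.64% of the total, lie in the 29243 transcripts. Reads in no feature make up 81.5% to 83.3% and reads without a unique position 14.6% to 16.7%, and these summary lines were left out of library sizes and tests. Tsix, antisense to Xist, had 2659 to 2779 reads but 0.12 to 0.20 FPKM, whereas Xist had 20 to 30 reads and 90.0 to 104 FPKM. Gapdh had 0 to 6 reads. Among genes with few fragments that overlap a gene on the other strand, the counts followed the partner's fragments (Spearman rho across genes 0.53 to 0.59) more closely than the gene's own (0.35 to 0.43). Genes are not independent replicates, so no p-value is given for these correlations. These values are those of a stranded library counted with the opposite strand setting. The test fixed before the data were examined was edgeR's quasi-likelihood test on these counts. Because of what the tables hold, and before any call was seen, it was replaced as the main test by the limma test on FPKM that had been listed as an alternative, and the edgeR test was run as written and is reported as an alternative.

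The main test was limma 3.58.1 with a trended prior on log2(FPKM + 1), for genes with an FPKM of at least 1 in at least 2 libraries, with Benjamini-Hochberg adjustment over 11348 genes and a threshold of 0.05. Tests were two-sided. The 22 gene lists, fixed before the data were examined, were tested with camera at a preset correlation of 0.01, adjusted over the lists. Of the 640 list entries 638 were found in the tables and 510 were tested. An estimated correlation and fry were alternatives. Fry tests whether the genes of a list move on balance one way, without comparison with other genes. Lists share some members, such as Ccnd1, Cdkn1a, Prl2c2, Sparc and Twist2.

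Depth was recovered from the FPKM tables. The upper confidence limit exceeds FPKM by 2 × FPKM divided by the square root of the fragment number, and solving for that number gave a whole number within 0.1 for 78.9% to 79.6% of genes with up to 200 fragments. The sum was 13304817 to 15733340 fragments per library. Replicates differed by more than counting noise, with a chi-square per degree of freedom over genes of 6.78 for the WT pair and 1.92 for the Tet2-KO pair, so they were not treated as repeat deposits of 1 library. This does not show that they came from separate cultures.

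Named genes followed a rule fixed before the data were examined. They were the tested Tet and Dnmt genes, the 8 higher and 8 lower genes with the largest log2 fold change past the threshold with at least 10 FPKM in the higher group and no overlap between groups, leaving out uncharacterised and short-RNA symbols, and per list up to 3 members past the threshold with the smallest adjusted p, with the members of highest mean added where fewer than 2 passed. The rule had named CPM (reads scaled to library size), and FPKM was used in its place. Other list members in the text were chosen as examples after their values were seen.

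Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a replicate block, each library left out, a test against a 1.2-fold change, an adjusted p under 0.01, and for the counts other size factors, filters and tests, among them DESeq2 1.42.0 and limma-voom. Added after seeing the data were a minimum of 5 FPKM, robust empirical Bayes, FPKM rescaled to equal medians, and edgeR 4.0.16 (with and without TMM) and DESeq2 on recovered fragment numbers. On simulated data for 10959 genes of the Tet2-KO against WT comparison, limma recovered 74% of genes changed 1.5-fold, 96% of those changed 2-fold and 100% of those changed 4-fold, and 5.61% of its calls were false. The simulation changed 50 genes at each fold, far fewer than were called in the data, and gave both groups the same spread. Its share of false calls need therefore not hold for the data. For a check of gene length and GC content, the longest transcript per symbol in GENCODE M21 was used. It gave a value for 94.7% of the tested genes. R 4.3.3, Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used.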

Results

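The data were poly(A)-enriched RNA-seq libraries from mouse trophoblast stem cells on a C57BL/6 background. Trophoblast stem cells are cultured precursors of the trophoblast, the lineage that builds the fetal part of the placenta, and they are kept undifferentiated by FGF4 and heparin. Both factors had been withdrawn for up to 7 days, and every library was labelled as day 7 of differentiation. The design held 2 wild-type (WT) libraries and 2 libraries labelled as Tet2 knockout (Tet2-KO). Tet2 encodes a dioxygenase that oxidises 5-methylcytosine in DNA, and the series also addressed these DNA modifications. The expression tables corresponded to 13304817 to 15733340 assigned fragments per library, and 10848 to 11057 genes per library reached 1 FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library). All values below are mean FPKM ± SD with n = 2 libraries per group, and log2 fold changes are Tet2-KO against WT on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. The labels did not say whether the replicates were separate cultures, so p-values measured only the spread between these samples. Both Tet2-KO libraries carried the name of a single knockout line, so genotype and cell line coincided. The names of their deposited tables call the knockout a double one, a term that the labels, which give only Tet2, do not explain. Whether it means both alleles of Tet2 or another gene as well is not known here.

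The targeted gene was examined first. Tet2 (chromosome 3, 133126641 to 133207354, mm9) was at 3.11 and 3.36 FPKM in the WT libraries and at 1.35 and 1.47 FPKM in the Tet2-KO libraries, a log2 fold change of -0.82 ± 0.09 (SE; limma adjusted p = 1.1e-04). The transcript was therefore lower but still measured in both Tet2-KO libraries. The value covers the whole gene, and the part of Tet2 that was disrupted is not stated in the labels. Tet3, a second dioxygenase of the family, fell from 12.5 ± 1.37 to 8.0 ± 0.56 FPKM (log2 fold change -0.58 ± 0.10 SE, limma adjusted p = 0.00104). Among the DNA methyltransferases, Dnmt3b fell from 4.05 ± 0.39 to 2.71 ± 0.23 FPKM. The limma test also called Dnmt1 (71.6 ± 6.82 against 58.2 ± 1.65 FPKM) and Dnmt3a (21.5 ± 1.57 against 18.4 ± 0.47 FPKM) lower. The Dnmt1 mean and call used the WT replicate 1 value of 66.8 FPKM, which had a failed status. Tested against a 1.2-fold change, none of these 3 passed (limma adjusted p = 0.15 for Dnmt3b, 0.72 for Dnmt1 and 1 for Dnmt3a). The Dnmt3a call was also lost with rescaled FPKM (limma adjusted p = 0.19). Without Tet2-KO replicate 1 neither Dnmt1 nor Dnmt3a passed (limma adjusted p = 0.0973 and 0.302), and Dnmt3a did not pass without WT replicate 2 (0.108) or Tet2-KO replicate 2 (0.18) either. Tet1 was at 0.78 ± 0.02 FPKM in WT and 0.34 ± 0.03 FPKM in Tet2-KO. It stayed under 1 FPKM in each library and was not tested.

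**Figure D1:**
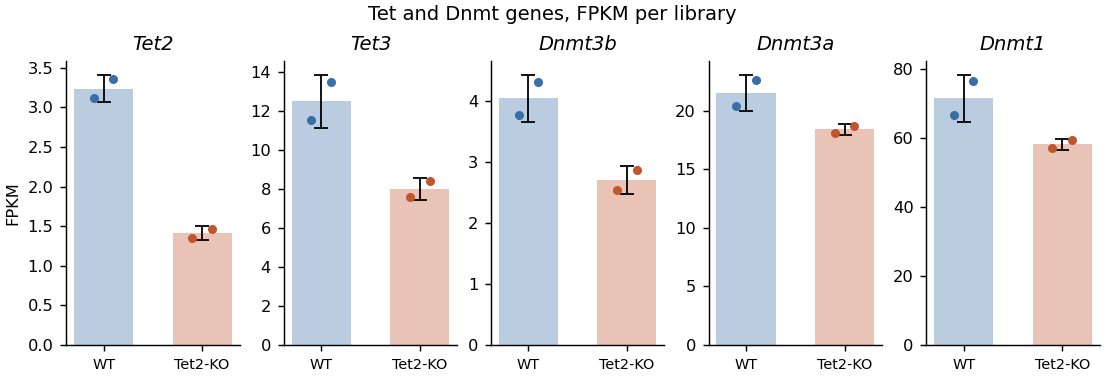
Expression in FPKM (vertical axes, each starting at 0) of Tet2, Tet3 and the 3 catalytic Dnmt genes in the WT and Tet2-KO groups. Points are the 2 libraries of each group, bars their mean and error bars the SD. Tet2 averaged 3.24 FPKM in WT and 1.41 FPKM in Tet2-KO libraries.

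The comparison of Tet2-KO with WT asked which transcripts differ between these cells after differentiation. In Tet2-KO cells 29 of 35 tested genes of the mesenchymal and invasion list were higher, and 19 of 24 spongiotrophoblast and glycogen cell genes, 17 of 21 labyrinth and syncytiotrophoblast genes, 25 of 31 hypoxia and glycolysis genes and all 36 mitotic genes were lower. Each of these lists passed camera with its preset correlation and none with an estimated one (adjusted p = 0.307 for the labyrinth list and 0.220 for the others). Of 15 tested fibroblast markers 13 rose beside these 5 lists. Acta2, smooth muscle actin, rose from 1.71 ± 0.25 to 78.6 ± 3.31 FPKM, and Serpine1, an inhibitor of plasminogen activators, rose from 108 ± 2.34 to 803 ± 9.40 FPKM. Tpbpa, the classical marker of the spongiotrophoblast lineage, fell from 97.4 ± 8.24 to 8.64 ± 0.35 FPKM. Limma with a trended prior called 6772 of 11348 tested genes at an adjusted p under 0.05, 2718 higher (24.0%) and 4054 lower (35.7%) in Tet2-KO. Of these, 662 were at least 2-fold higher and 583 at least 2-fold lower, and 138 and 65 were at least 4-fold higher and lower. The median log2 fold change of all tested genes was -0.09, and after rescaling every library to equal medians the calls split into 3324 higher and 3278 lower (3067 and 2798 with DESeq2 on fragment numbers recovered from the FPKM tables). Tested against a change of at least 1.2-fold, 3551 genes remained. The edgeR test on the deposited count tables, which hold few reads per gene, called 1069 of 5070 tested accessions. These counts are like those of a library counted with the opposite strand setting. Of 2639 genes called by the main test and tested there, 844 were called by both tests, 825 of them in the same direction. Both tests used the same libraries, so this is not independent support.

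The 8 genes with the largest rises were Mgp, Hn1, Acta2, Cryab, Ctgf, Bgn, Spp1 and Cyr61. Mgp (matrix Gla protein, chromosome 6, 136820956 to 136824326, mm9), an inhibitor of tissue calcification, rose from 2.15 ± 1.16 to 204 ± 6.74 FPKM, with a log2 fold change of 6.08 ± 0.20 (SE; limma adjusted p = 9.7e-08). Cryab, a small heat shock protein, went from 8.58 ± 0.33 to 254 ± 1.17 FPKM, and Spp1 (osteopontin) from 14.6 ± 0.33 to 341 ± 4.06 FPKM. The proteoglycan gene Bgn increased from 4.65 ± 0.20 to 133 ± 4.21 FPKM. The 8 largest falls were those of Srd5a1, Ghrh, Rarres2, Plbd1, Prl2b1, Upp1, Nrgn and Tpbpa. Srd5a1, a steroid reductase (chromosome 13, 69712327 to 69750341, mm9), fell from 59.8 ± 1.37 to 0.76 ± 0.10 FPKM, with a log2 fold change of -5.11 ± 0.09 (SE; limma adjusted p = 5.2e-09). Ghrh, which encodes growth hormone-releasing hormone, fell from 631 ± 28.4 to 22.2 ± 2.68 FPKM, and Rarres2, the gene of the secreted chemoattractant chemerin, from 303 ± 11.7 to 12.6 ± 0.81 FPKM.

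**Figure D2:**
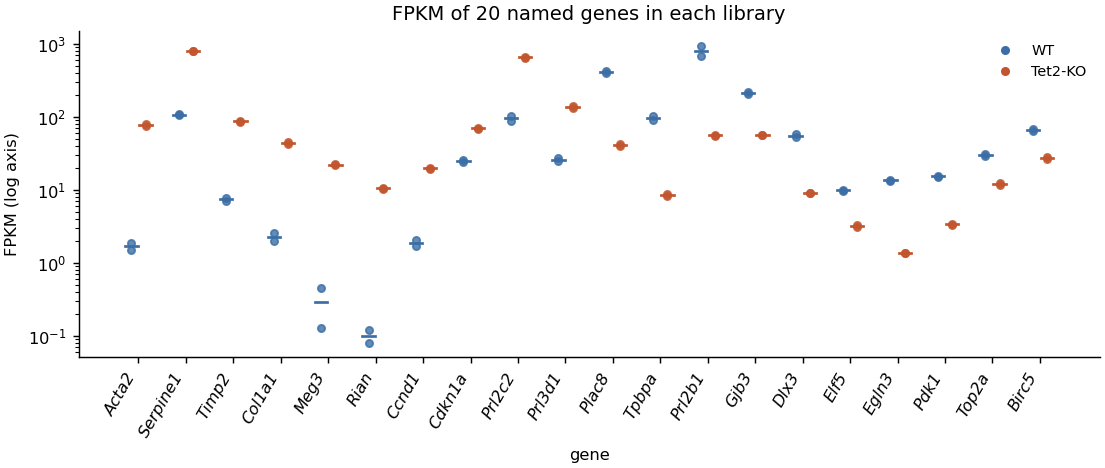
FPKM of 20 named genes (vertical axis, logarithmic) in the 2 WT and the 2 Tet2-KO libraries. Points are libraries and short lines are group means. The groups do not overlap for any of the 20 genes, for example Meg3 at a mean of 0.29 FPKM in WT and 22.2 FPKM in Tet2-KO.

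Of 35 tested genes of the mesenchymal and invasion list, 29 rose and 4 fell, with a median log2 fold change of 1.49 (1.202 to 2.35 over its alternatives; camera adjusted p = 2.4e-13), and the counts adjusted over the list alone were 29 and 5. The camera adjusted p was 0.220 with an estimated correlation. Besides Acta2 and Serpine1, the metalloproteinase inhibitor Timp2 rose from 7.50 ± 0.53 to 87.8 ± 1.75 FPKM and the intermediate filament gene Vim from 37.1 ± 0.80 to 190 ± 0.60 FPKM. Mmp9, Itgb3, Snai1 and Tgfb1 fell, Snai1 from 56.2 ± 5.80 to 37.5 ± 0.71 FPKM, while Fn1 was at 390 FPKM in WT and 414 FPKM in Tet2-KO. Markers of fibroblasts rose in the same comparison. With only WT and Tet2-KO libraries compared, genes that change for unrelated reasons also move together. Of 15 tested fibroblast markers 13 rose and 1 fell, also when adjusted over the list alone, with a median log2 fold change of 2.85 (camera adjusted p = 5.2e-10). Their camera adjusted p was likewise 0.220 with an estimated correlation. Fbln2 rose from 1.93 ± 0.08 to 53.4 ± 0.76 FPKM, and the collagen genes Col1a1 and Col1a2 reached 44.2 ± 1.31 and 40.0 ± 1.3 FPKM in Tet2-KO. Pdgfra fell from 13.9 ± 0.03 to 9.81 ± 0.05 FPKM.

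Of 19 tested angiogenic factors and receptors 12 rose and 6 fell, with a median log2 fold change of 1.32 (camera adjusted p = 7.7e-04), and the counts were the same adjusted over the list alone. With an estimated correlation the camera adjusted p was 0.315. The median fell to 0.25 without Tet2-KO replicate 1 and 0.18 without Tet2-KO replicate 2, and rose to 2.31 with a pseudocount of 0.1 and 2.30 with edgeR (TMM) on recovered fragments. Leaving out a Tet2-KO library also dropped any gene under 1 FPKM in both WT libraries. The matricellular genes Ctgf, Cyr61 and Thbs1 had the smallest adjusted p of the list, and Thbs1, an inhibitor of angiogenesis, rose from 3.65 ± 0.34 to 73.6 ± 0.20 FPKM. Pgf, placental growth factor, fell from 7.08 ± 0.18 to 2.39 ± 0.36 FPKM. Of 23 extraembryonic endoderm markers only 10 were high enough to be tested. Sox17 averaged 0.015 and 0.018 FPKM and Afp 0.027 and 0 FPKM in WT and Tet2-KO, and neither was tested. Of the 10 tested endoderm markers 8 rose and 1 fell, over all genes and adjusted over the list alone (median log2 fold change 0.64, 0.57 to 1.07 over its alternatives, camera adjusted p = 0.0011). Their camera adjusted p was 0.279 with an estimated correlation. The rise was led by the basement membrane collagens Col4a1, from 54.4 ± 5.77 to 253 ± 5.34 FPKM, and Col4a2, while the transferrin gene Trf fell from 9.68 ± 0.98 to 1.00 ± 0.22 FPKM. Both changes came in the same comparison as the rise of 13 fibroblast markers, and a link was not tested.

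Of 24 tested spongiotrophoblast and glycogen cell genes 19 fell and 1 rose, also adjusted over the list alone, with a median log2 fold change of -0.87 (camera adjusted p = 1.1e-05). With an estimated correlation the camera adjusted p was 0.220. Prl2b1, of the placental prolactin family, fell from 815 ± 176 to 56.0 ± 1.70 FPKM, and the connexin gene Gjb3 from 216 ± 10.7 to 56.9 ± 0.26 FPKM. In the labyrinth and syncytiotrophoblast list 17 of 21 genes fell and 2 rose, also adjusted over the list alone (median log2 fold change -0.86, camera adjusted p = 2.7e-04). Here the camera adjusted p was 0.307 with an estimated correlation. The transcription factor gene Dlx3 fell from 55.8 ± 4.68 to 9.24 ± 0.01 FPKM, and Hsd11b2, which inactivates glucocorticoids, from 43.7 ± 2.89 to 11.2 ± 0.20 FPKM. Met, the hepatocyte growth factor receptor gene, and its regulator Spint1 rose. Gcm1, a regulator of syncytiotrophoblast formation, stayed under 1 FPKM in each library. Both falls came in the same comparison as the rise of 13 of 15 fibroblast markers (median log2 fold change 2.85), and a link was not tested.

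Trophoblast giant cell genes went both ways, with 12 of 22 higher and 9 lower over all genes and adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0786). It passed with a minimum of 5 FPKM (camera adjusted p = 0.0377) and with a replicate block (0.0373). It did not pass with rescaled FPKM (camera adjusted p = 0.173), no filter (0.214), edgeR (TMM) on recovered fragments (0.348) or an estimated correlation (0.734). Its median log2 fold change was 0.38, and 0.31 to 0.38 when a library was left out. Prl2c2, a proliferin gene, rose from 96.0 ± 10.8 to 660 ± 18.4 FPKM, and Prl3d1, placental lactogen I, from 26.1 ± 1.86 to 136 ± 6.18 FPKM. Hand1, a transcription factor gene required for giant cell formation, rose from 520 ± 40.5 to 704 ± 28.9 FPKM. Plac8 fell from 414 ± 24.7 to 41.4 ± 2.03 FPKM, Prl3b1 (placental lactogen II) from 655 ± 42.1 to 183 ± 1.18 FPKM, and the placental cathepsin gene Ctsq from 406 ± 63.1 to 141 ± 8.47 FPKM. Near-identical copies share reads in the Prl2c and Prl3d families and in the Psg, Rhox and Xlr families, so values of single members are uncertain. Of 16 tested trophoblast stem cell genes 10 fell and 3 rose (11 and 3 adjusted over the list alone). Among the falls were the stem cell regulators Elf5, from 9.97 ± 0.24 to 3.23 ± 0.19 FPKM, and Satb1, from 9.40 ± 0.23 to 1.72 ± 0.14 FPKM. Ddah1 of the same list rose from 0.24 ± 0.09 to 3.14 ± 0.16 FPKM. That list lay just outside the threshold (camera adjusted p = 0.0545). It passed with rescaled FPKM (camera adjusted p = 0.0261), no filter (0.0085), a minimum of 5 FPKM (0.0036) and edgeR (TMM) on recovered fragments (0.0174). It did not pass with a replicate block (camera adjusted p = 0.0542) or an estimated correlation (0.487). Its median log2 fold change was -0.51, and -0.57 to -0.39 when a library was left out. These changes too stood beside the rise of 13 of 15 fibroblast markers.

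All 36 tested mitotic genes fell, also adjusted over the list alone, with a median log2 fold change of -0.94 (camera adjusted p = 2.5e-10). The camera adjusted p was 0.220 with an estimated correlation. Birc5 (survivin) fell from 66.7 ± 3.76 to 27.9 ± 1.33 FPKM and Top2a, a topoisomerase of dividing cells, from 30.6 ± 1.40 to 12.2 ± 0.62 FPKM. Among DNA replication and endocycle genes 21 of 34 fell and 8 rose (22 and 8 adjusted over the list alone). That list did not pass (median log2 fold change -0.32, camera adjusted p = 0.184). Without a filter its camera adjusted p was 0.0204, and with an estimated correlation 0.426. The rises included the D-type cyclins Ccnd1, from 1.87 ± 0.26 to 19.8 ± 0.47 FPKM, and Ccnd2, from 0.41 ± 0.03 to 11.7 ± 0.19 FPKM, and the inhibitors Cdkn1a, from 25.1 ± 1.03 to 69.9 ± 1.10 FPKM, and Cdkn1c, from 877 ± 45.7 to 1430 ± 4.89 FPKM. Of 24 p53 target genes 16 rose and 4 fell, also adjusted over the list alone (median log2 fold change 0.61, camera adjusted p = 3.9e-05), with Phlda3 at 23.8 ± 1.17 and 91.4 ± 1.82 FPKM and Mdm2 at 59.5 ± 0.07 and 122 ± 0.32 FPKM in WT and Tet2-KO. Their camera adjusted p was 0.220 with an estimated correlation. FGF and ERK response genes rose in 13 of 23 cases and fell in 7 (13 and 8 adjusted over the list alone; median log2 fold change 0.48, camera adjusted p = 0.0265). That call was lost with an estimated correlation (camera adjusted p = 0.678), without WT replicate 1 (camera adjusted p = 0.0588) and with rescaled FPKM (camera adjusted p = 0.0575), no filter (0.0666), a minimum of 5 FPKM (0.18) or edgeR (TMM) on recovered fragments (0.0627). Its median was 0.16 without either Tet2-KO library or with that minimum, 0.85 with edgeR and 0.76 with a pseudocount of 0.1. Leaving out a Tet2-KO library also dropped any gene under 1 FPKM in both WT libraries. Fos, an immediate early gene, rose from 42.0 ± 1.59 to 97.4 ± 0.90 FPKM, while Fgfrl1 fell from 25.6 ± 1.16 to 8.85 ± 0.33 FPKM. Beside these falls and rises, of mitotic genes, D-type cyclins, p53 targets and FGF and ERK response genes, 13 of 15 fibroblast markers rose. A link was not tested.

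Hypoxia and glycolysis genes fell in 25 of 31 cases and rose in 2, also adjusted over the list alone, with a median log2 fold change of -1.02 (camera adjusted p = 2.6e-07). With an estimated correlation the camera adjusted p was 0.220. The prolyl hydroxylase gene Egln3, a target of hypoxia-inducible factors, fell from 13.6 ± 0.54 to 1.37 ± 0.01 FPKM, and Pdk1, an inhibitor of pyruvate dehydrogenase, from 15.5 ± 0.23 to 3.38 ± 0.05 FPKM. The glycolytic genes Aldoa (735 ± 61.3 to 355 ± 17.4 FPKM), Ldha (312 ± 0.89 to 157 ± 1.00 FPKM) and Gapdh (487 ± 7.57 to 266 ± 8.96 FPKM) fell as well. Hif1a was at 65.3 ± 5.74 FPKM in WT and 64.5 ± 2.88 FPKM in Tet2-KO, and Vegfa rose from 18.9 ± 0.91 to 24.8 ± 0.07 FPKM. Cytosolic ribosomal protein genes, which share reads with processed pseudogenes, fell in 32 of 38 cases and rose in 0, also adjusted over the list alone (median log2 fold change -0.38, camera adjusted p = 6.7e-06), Rps20 from 713 ± 46.6 to 442 ± 26.5 FPKM. Their camera adjusted p was 0.220 with an estimated correlation. The hypoxia, glycolysis and ribosomal protein genes fell while 13 of 15 fibroblast markers rose.

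Imprinted genes, which are expressed from 1 parental allele, rose in 20 of 39 cases and fell in 11 (21 and 12 adjusted over the list alone), with a median log2 fold change of 0.20 (camera adjusted p = 0.0041). That call was lost with an estimated correlation (camera adjusted p = 0.264), without Tet2-KO replicate 1 (camera adjusted p = 0.210), without Tet2-KO replicate 2 (0.311) and with edgeR on recovered fragments (0.069 with TMM). Without Tet2-KO replicate 1 the median turned to -0.0028, and without Tet2-KO replicate 2 it was 0.039. Leaving out a Tet2-KO library also dropped genes under 1 FPKM in both WT libraries, among them Meg3 and Rian. These medians therefore leave out strong rises. Meg3 (chromosome 12, 110779206 to 110809939, mm9) rose from 0.29 ± 0.23 to 22.2 ± 0.53 FPKM, and Rian (chromosome 12, 110842155 to 110899921, mm9) from 0.10 ± 0.03 to 10.5 ± 0.17 FPKM. Both are maternally expressed noncoding RNAs of the same imprinted cluster, whose protein-coding gene Dlk1 was at 0.55 ± 0.16 and 0.68 ± 0.005 FPKM. Dio3, at the far end of that cluster, fell from 7.66 ± 1.45 to 1.93 ± 0.17 FPKM. Cd81 rose from 7.98 ± 1.17 to 85.5 ± 4.52 FPKM, whereas Plagl1 fell from 21.7 ± 1.5 to 3.37 ± 0.33 FPKM and Phlda2, a restrainer of placental growth, from 312 ± 24.4 to 161 ± 3.56 FPKM. The 13 fibroblast markers rose in the same comparison as Meg3, Rian and Cd81, and a link was not tested.

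The remaining lists did not pass. Their counts are to be read beside the shares over all tested genes, of which 24.0% were called higher and 35.7% lower. Of 15 DNA methylation and demethylation enzymes 9 fell and 1 rose (camera adjusted p = 0.0606). That list passed without a filter (camera adjusted p = 0.0139) and with edgeR (TMM) on recovered fragments (0.0435). It did not pass with a minimum of 5 FPKM (camera adjusted p = 0.152) or an estimated correlation (0.426). Its median log2 fold change was -0.33, and -0.39 to -0.31 when a library was left out. The CXXC-domain gene Cxxc5 was at 23.8 ± 0.82 and 9.79 ± 0.76 FPKM and Ogt at 66.0 ± 3.95 and 41.0 ± 2.71 FPKM. Epithelial genes rose in 12 and fell in 10 of 30 cases (camera adjusted p = 0.209, and 0.790 with an estimated correlation). Their median log2 fold change was 0.021, and 0.030 without Tet2-KO replicate 1. Cldn4, a tight junction gene, rose from 68.5 ± 2.88 to 305 ± 8.51 FPKM, and Cdh1 (E-cadherin) was at 55.1 ± 1.81 and 54.8 ± 2.47 FPKM. Of 28 steroid and lipid synthesis genes 13 fell and 5 rose (camera adjusted p = 0.606), but the steroidogenic genes Star (3.78 ± 0.03 to 15.7 ± 0.52 FPKM), Hsd3b6 (8.34 ± 0.63 to 34.6 ± 0.02 FPKM) and Cyp11a1 (68.1 ± 1.06 to 143 ± 2.67 FPKM) were among the rises. Of 29 interferon response genes 13 fell and 5 rose (camera adjusted p = 0.351), Rsad2 from 38.0 ± 3.05 to 15.4 ± 1.00 FPKM. Blood and endothelial markers had 2 rises and 3 falls among 5 tested (camera adjusted p = 0.741), with the macrophage marker Cd68 at 17.4 ± 1.37 and 59.8 ± 7.76 FPKM and the endothelial cadherin gene Cdh5 at 167 ± 14.6 and 54.5 ± 1.58 FPKM. These counts of 5 lists were the same adjusted over the list alone. Of the 41 genes found from the list of germline genes known as targets of silencing by DNA methylation, 30 were too low to be tested. The 11 tested reached 1 FPKM in at least 2 libraries, some of them already abundant, such as Rhox6 at 1905 ± 104 FPKM and Rhox9 at 1662 ± 133 FPKM in WT, and 4 of them rose and 5 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.720), with a median log2 fold change of -0.12 (-0.48 to -0.03 over its alternatives) and a mean of 0.11. Tex13 rose from 0.54 ± 0.09 to 9.14 ± 0.73 FPKM, and Tdrkh fell from 9.03 ± 0.68 to 2.66 ± 0.03 FPKM. Ddx4 stayed under 1 FPKM in each library. Embryonic stem cell and epiblast markers had 2 rises and 2 falls among 5 tested (3 and 2 adjusted over the list alone; camera adjusted p = 0.663).

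**Figure D3:**
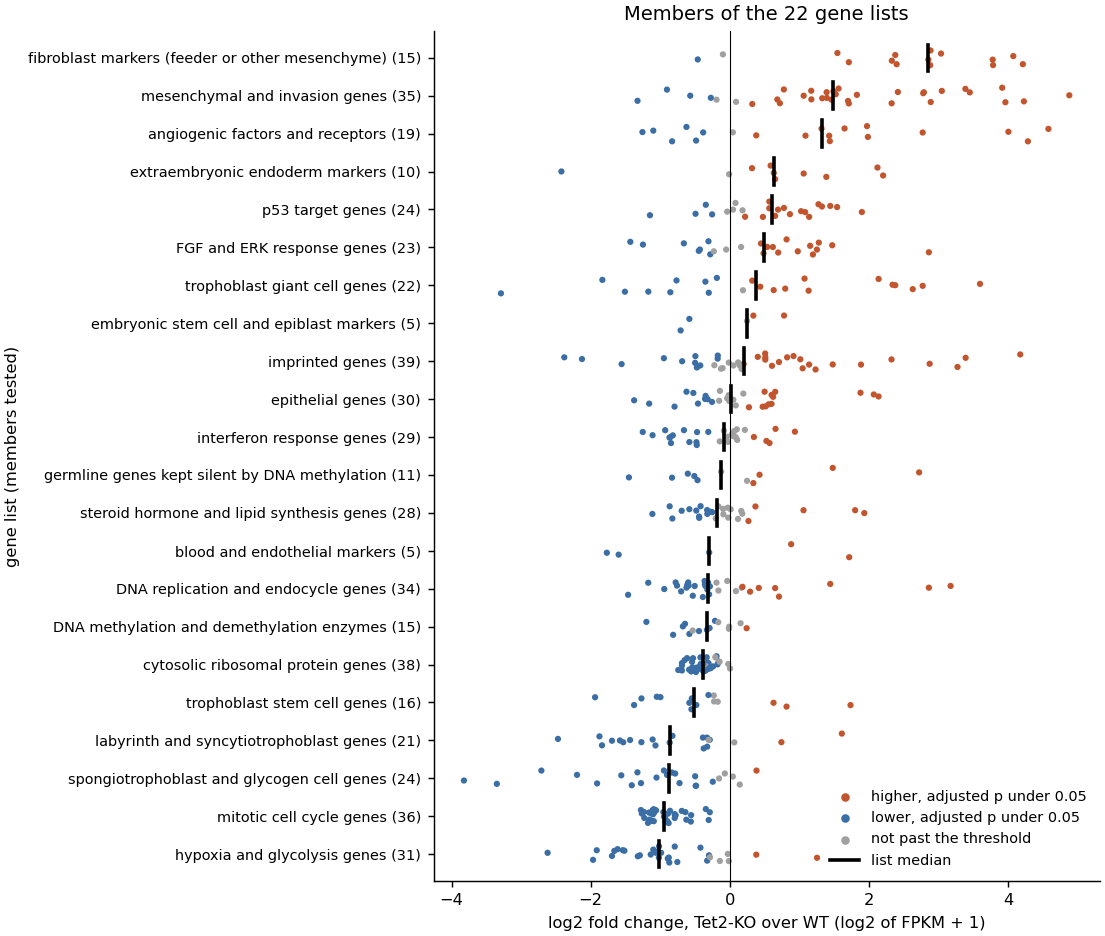
Log2 fold change of Tet2-KO over WT on the log2(FPKM + 1) scale (horizontal axis) for the tested members of the 22 gene lists (vertical axis, number of members tested in brackets). Points are genes, coloured by whether limma called them higher, lower or neither at an adjusted p under 0.05, and black lines are list medians. Medians run from -1.02 for hypoxia and glycolysis genes to 2.85 for fibroblast markers.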

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

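The loci below and the tests of scaling, fibroblast markers, cell line, replication genes and gene copies were chosen after the values had been seen, and the test of gene length and GC content was set before its result was seen.

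Loci without a gene symbol were outside the tests, and 3 of them were at 5 FPKM or more in both Tet2-KO libraries and at least 2-fold above both WT libraries. On chromosome 14, the locus from 26882537 to 26886911 (mm9) averaged 9.97 ± 0.21 FPKM in Tet2-KO and 2.45 ± 0.35 FPKM in WT. The locus from 27022153 to 27026527 on the same chromosome averaged 18.5 ± 1.16 FPKM in Tet2-KO and 4.53 ± 0.08 FPKM in WT. The nearest named genes were Duxbl3, 72.9 kb away, and Plac9a, 20.4 kb away. Both chromosome 14 loci span the same length, and whether they are copies that share reads was not tested. On chromosome 7, the locus from 134119902 to 134124015, which overlaps Cdipt, averaged 14.1 ± 0.19 FPKM in Tet2-KO and was at 5.61 and 0.0052 FPKM in the WT libraries.

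The first pattern was the rise of mesenchymal and invasion genes in Tet2-KO cells. The scaling of the FPKM values was argued against, since the lowest list median under 3 other scalings was still 1.53. Fibroblasts among the Tet2-KO cells remain a candidate source, because 13 of 15 tested markers on the fixed fibroblast list rose. Of the 15, 11 were at 1 FPKM or more in WT cells, and 1 is shared with the mesenchymal list. The count cannot tell added fibroblasts from a rise of the same genes within the trophoblast cells. The fibroblast genes Dcn and Lum, too low to be tested, averaged 0.17 and 0.024 FPKM in WT and 1.01 and 0.44 FPKM in Tet2-KO. Thy1 and Prrx1 rose, Prrx1 from 0.147 to 7.445 FPKM, and Col1a1 was at 44.2 FPKM in Tet2-KO, while Pdgfra fell. Pdgfrb, at 7.63 ± 0.93 FPKM in WT and 7.04 ± 0.60 FPKM in Tet2-KO, was not called. An effect of losing Tet2 and a property of the line cannot be told apart, because the labels name 1 Tet2-KO line, and the table names calling it a double knockout leave disruption of another gene open.

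The second pattern was the fall of all 36 tested mitotic genes. Scaling was argued against by a list median of -0.87 in the scaling that brought it closest to 0, and gene length and GC content by a median of -0.93 (quartiles -1.13 and -0.79) after the trend with both was removed. A hypothesis is that fewer cells divided while DNA replication was less affected, as in the endocycle of giant cells. The median of replication and endocycle genes lay 0.62 above that of mitotic genes on the log2 scale. Permutation of genes between the lists gave p = 1e-05, the smallest that 100000 permutations can give. However, genes are not independent. Only the replication and endocycle list also holds the D-type cyclins and their inhibitors, so they bear on its median alone. Both medians had been seen before this test. The difference cannot tell an endocycle from another fall in division. A changed mix of cells, with 13 of 15 fibroblast markers higher, was not tested for this pattern and stays open. The single Tet2-KO line leaves the origin of this difference open too.

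The third pattern was the rise of proliferin and placental lactogen I genes while some other giant cell genes fell. Further ones, such as Hand1 and Prl2a1, rose as well. Reads moving between near-identical copies were argued against as the whole cause, because the summed FPKM of 4 Prl2c copies was 570 ± 102 in WT and 1290 ± 87.2 in Tet2-KO, and that of 3 Prl3d copies 80.4 ± 10.8 and 405 ± 19.2. The lower Tet2-KO library exceeded the higher WT library by at least 1.91-fold in both sums. A different mix of giant cell types without Tet2 was not tested and stays open, as does the cell line.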

How the results depend on the processing

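The alternatives using recovered fragments, rescaled or filtered FPKM and robust empirical Bayes were chosen after seeing the data. Tet2 stayed lower and past the threshold in each FPKM and recovered-fragment fit, with log2 fold changes of -0.86 to -0.77 when a library was left out; the 5 FPKM filter and the count tests gave no value for it. The 6772 calls became 3551 against a 1.2-fold change, 1069 on the deposited counts, and 4668 to 6866 when a library was left out. Without Tet2-KO replicate 1 or 2 the higher genes fell from 2718 to 1680 or 1645; 6307 of the called genes then met the filter, and the lone library was assumed to vary like the others. Recovered fragments gave 7375 calls with edgeR and TMM and 5865 with DESeq2, whose median log2 fold change over all genes was 0.04 against -0.09 in the main test. On the deposited counts the 1069 calls became 266 with DESeq2 and 650 to 811 when a library was left out. The cause was not tested. Dnmt3a reversed there, to 0.13 (edgeR adjusted p = 0.761). Those counts are like those of a library counted with the opposite strand setting. The value need therefore not follow the Dnmt3a transcript, which was not tested. Over the 16 alternatives to the main limma test of Dnmt3a, this count fit among them, the adjusted p ran from 0.0085 to 1. The 12 lists past the threshold became 0 with camera's estimated correlation, 18 with fry, and 12 to 14 when a library was left out. No list has an estimated-correlation adjusted p under 0.220. The labels state no shared batch for replicate numbers. A replicate block gave 7651 calls, 1028 on the counts, 13 lists, adding trophoblast giant cell genes (camera adjusted p = 0.0373), and a Tet2 log2 fold change of -0.82. Same-numbered libraries deviated together (correlation across genes 0.30), which 2 pairs cannot establish as pairing. Across the values of single genes, lists and calls per direction, 2022 kept their direction and call or size, 77 lost a call, 24 gained one, 13 counts of higher or lower genes moved by over 1.5 times and 4 reversed, Dnmt3a and the medians of 3 lists. Those were epithelial genes (from 0.021 to -0.017 without WT replicate 1, with up to 0.064 without another library), imprinted genes (from 0.20 to -0.0028 without Tet2-KO replicate 1, with up to 0.26 without another) and interferon response genes (from -0.084 to 0.0038 with rescaled FPKM). With 1 Tet2-KO library left, the filter dropped genes under 1 FPKM in both WT libraries, among them the imprinted Meg3 and Rian. Causes were not tested beyond that. The count tests rest on 304171 to 349278 reads in transcripts, out of 19992107 to 24569886 per table.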

Other observations

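The genes in this paragraph were chosen after their values were seen. Slc38a4, an imprinted amino acid transporter gene, fell from 421 ± 5.47 to 58.1 ± 0.32 FPKM, and the protease gene Pappa2, which acts on IGF-binding proteins, from 11.2 ± 0.21 to 0.29 ± 0.04 FPKM. The receptor gene Kit fell from 26.2 ± 0.38 to 3.83 ± 0.42 FPKM, the epithelial transcription factor gene Elf3 from 134 ± 9.44 to 16.2 ± 0.17 FPKM, and the connexin gene Gjb5 from 177 ± 2.59 to 25.8 ± 1.36 FPKM. Igfbp2 rose from 9.70 ± 0.62 to 122.8 ± 2.92 FPKM, Pdgfb from 13.3 ± 0.62 to 78.0 ± 2.80 FPKM, Csf1 from 2.66 ± 0.09 to 23.0 ± 0.58 FPKM, the chemokine gene Ccl2 from 1.05 ± 0.03 to 12.4 ± 1.06 FPKM and tissue factor, F3, from 13.7 ± 1.08 to 91.0 ± 1.77 FPKM. The matrix gene Tnc and the BMP antagonist gene Grem1 reached 29.1 ± 0.70 and 15.1 ± 0.28 FPKM from 0.87 ± 0.03 and 0.24 ± 0.25 FPKM. Limma called each of these genes changed, with the largest adjusted p at 1.5e-07.

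Over 7443 genes with at least 5 FPKM in both groups, the median log2 fold change per chromosome lay between -0.18 and 0.03 on 20 chromosomes. The first principal component of log2(FPKM + 1) held 94.9% of the variance and separated the groups, and the correlation across genes was 0.995 within WT, 0.997 within Tet2-KO and 0.920 to 0.921 between groups. The groups did not overlap for 80.1% of tested genes, where chance gives 33.3% for 2 against 2.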
